A study of Drosophila melanogaster with 2 samples.

How the data were processed

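The series measured the binding of CG3847 by chromatin immunoprecipitation and sequencing in whole embryos of Drosophila melanogaster, 0 to 24 h old. Per the labels, the flies expressed CG3847 fused to eGFP, the precipitation used an antibody against GFP, and chromatin was sheared by sonication to fragments of 200 to 800 bp. The 2 libraries are biological replicates 1 and 2 of 1 group, with the numbers taken from the labels. The control experiment that the labels point to was not used here.

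The authors deposited 4 thresholded peak sets and 4 ranked peak tables on assembly dm6, all made with the irreproducible discovery rate (IDR), a method that keeps peaks ranked alike in 2 sets of data. Per the deposited file descriptions, the replicate sets come from the alignments of each replicate, and the optimal and conservative sets from those of both, and an exclusion list of regions entered the thresholded sets. The aligner, the peak caller, their versions and the control subtraction are not given in the sources used here. The deposited score is the IDR scaled to at most 1000, and its lowest value in each thresholded set was 830, as a global IDR of 0.01 gives. The deposited signal is the peak caller's value for a peak, with a scale that is not given in the sources used here, and it was used to describe, rank and filter peaks and to compare the 2 component peaks of a ranked row. The ranked tables hold −log10 of the global IDR, as deposited by the authors, up to 5, and other deposited columns give the summit's offset from the peak start in bp. The p-value column of the deposited files is empty, so no peak has a p-value here. The ranked table of the replicates holds the signals of both replicates without their numbers. Read counts and depth are not given in the sources used here, so intervals on shares cover the counting of peaks or genes only.

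Peaks were analysed on 2L, 2R, 3L, 3R, 4, X and Y, which hold 6148 of the 6174 optimal peaks, and every peak lay within the chromosome lengths of the Release 6 reference. Genes were taken from Ensembl release 115, which carries the FlyBase 6.54 annotation, without transposable elements, giving 18277 genes and 23694 distinct TSS positions. A summit took the first class that applied of TSS-proximal (within 500 bp of any TSS), 5′ UTR, coding exon, 3′ UTR, other exon, intron and intergenic. Shares per class were tested with an exact two-sided binomial test against the share of bases, weighted by the number of summits per chromosome, and shares per chromosome against length. Peak signal was compared between proximal and distal peaks with 100000 permutations of the difference of medians.

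Gene lists were fixed before the data were examined: 22 lists of protein-coding genes and 6 lists by gene type, the former tested against the other protein-coding genes and the latter against all other genes with Fisher's exact test. Members without a match in the annotation were dropped. Log2 odds ratios used 0.5 added to each cell. Divergent genes have a head-to-head protein-coding TSS within 1000 bp. Motif windows of 200 bp at summits were compared with windows at ranked summits that no thresholded set contains, drawn up to 2 per summit in bins of 5% GC content and by TSS proximity. For 22 known consensus motifs p-values were adjusted with Benjamini-Hochberg, and 8-mers were found on 2L, 3L, X and 4 and tested on 2R and 3R with Bonferroni adjustment. A threshold of 0.05 on adjusted p was used throughout. Tests across peaks, genes or windows treat these as independent, which neighbouring ones are not, and say nothing of the spread between embryos.

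The rule for named genes was fixed before the data were examined. It takes CG3847, the 25 genes with the strongest promoter peak that overlaps the conservative and both replicate sets, the 5 strongest such peaks without a TSS within 500 bp, up to 4 bound members of each list past the threshold and up to 2 of each other list. A peak names the gene with the nearest TSS.

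The replicates were compared by peak overlap of at least 1 bp, by the correlation of signals and by the spread of their log2 ratio beside that of pseudoreplicates, which are random splits of a library. For each optimal peak, the ranked peak with the highest signal that overlaps it was used. This matching was not fixed in advance: it was chosen after the data were examined, and after a version with 2 other choices, rows of identical coordinates and pseudoreplicates over each library's own thresholded peaks, had given a higher ratio of spreads. An interval for the ratio of spreads came from 1000 bootstrap samples of peaks. Alternatives were the conservative set, a stricter IDR, the stronger 50% of the peaks, each replicate left out (the thresholded set of the other replicate alone), TSS windows of 200 and 1000 bp, 1 TSS per gene, other backgrounds and other overlap rules. A global IDR of 0.001, the merging of overlapping peaks, a background of genes with a ranked peak near a TSS, another matching of rows and another peak set for the pseudoreplicates were added after seeing the data.

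The tests were also run on simulated data, after the first look at the deposited files. For the TSS-proximal share, 4 of 100 sets of uniform summits were called, and with 20% of 5000 summits planted at TSSs the recovered share was 20.0%. For the gene lists, 27 of 2200 list tests were called with no list changed, and a list with 60% of genes bound was called in 85 of 100 simulations with 30 genes and in 99 with 80 genes. For the 8-mers, with both groups of windows drawn from the same pool of ranked peaks, none passed without a planted word in 5333 windows. A word planted in 4% of them was recovered, with 7 8-mers passing in all, so 1 element can make several 8-mers pass. For the difference of medians, 8 of 100 simulations without a difference were called. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.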

Results

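Chromatin immunoprecipitation followed by sequencing was used to map where the protein of CG3847 sits on the genome of Drosophila melanogaster embryos collected 0 to 24 h after egg laying. The embryos were transgenic and carried CG3847 fused to enhanced green fluorescent protein (eGFP), and chromatin was precipitated with an antibody against GFP. The series holds 1 group with 2 biological replicates, so it contains no comparison between conditions, and control libraries were not used here. Binding of CG3847 was therefore not told apart from signal that does not depend on it. The question addressed is which genes, regions and sequence elements lie under the peaks, and how far the 2 replicates give the same ones. Peaks, not reads, were analysed, and read depth per library is not given in the sources used here. All positions are on assembly dm6 and are counted from 1.

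At the promoter of CG3847 itself (FBgn0029867, X:6347103-6349236, plus strand) a peak spanned X:6346856-6347256, with its summit 65 bp upstream of the transcription start site (TSS) in intergenic sequence. Its signal, the peak caller's own value in the deposited list, was 1194 in the pooled optimal set, which ranked 51 among 6148 peaks on the major chromosomes. The value was 448 in the list of replicate 1 and 745 in that of replicate 2. Ranked peaks within 10 kb of the gene, leaving out those at its promoter, also had a high median signal of 62.5, against a median of 20.1 over 986 windows of the same length on X.

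The strongest promoter peak lay at CG14100 (FBgn0036889, 3L:19589072-19590524), with a pooled signal of 3804 and a summit 89 bp upstream of the TSS. Peaks at Ugalt, which encodes a UDP-galactose transporter (FBgn0024994, X:2701124-2703852, summit 29 bp upstream), and at mRpL41, a mitochondrial ribosomal protein gene (FBgn0034001, 2R:15217024-15217617, summit 135 bp upstream), followed with signals of 3121 and 3062. For these 3 genes the replicate lists gave 2162 and 1659, 1769 and 1375, and 1615 and 1479 for replicates 1 and 2. The other 22 of the 25 promoters taken by the rule for named genes had pooled signals from 2356 at CG5611 down to 1451 at CG18549. They comprised Tcs5, the Polycomb group gene ph-p, Art3, lncRNA:CR44619, asRNA:CR45928, Shc, PNPase, SLC5A11, Fkbp14, CenG1A, the chromodomain gene Chro, CG7601, CG8320, CG13390, mRpL23, px, GstE13, gish, Arl1 and CG1888, besides CG5611 and CG18549. Several of these peaks lay near the starts of 2 genes: the peak named for CG5611 was also within 500 bp of a TSS of Mtl, that of Tcs5 of CHMP2B, that of Art3 of mRpS10, that of asRNA:CR45928 of the translation factor gene eIF6, and that of Arl1 of brm, the ATPase of a chromatin remodelling complex. The rule itself required all 25 to be in the conservative set and in both replicate sets, so their presence there is no result. All 25 had the higher value in the list of replicate 1, whereas the CG3847 peak had the higher value in that of replicate 2.

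The 5 strongest peaks found in every set without a TSS within 500 bp were all intronic. The strongest peak of the whole set, with a signal of 4117, lay at 2L:6612435-6612957 in an intron of CG11050, 1025 bp downstream of the nearest TSS, with 2171 and 1948 in the lists of replicates 1 and 2. A peak at 2R:21703100-21703676 with a signal of 2481 lay in intronic sequence within the annotated spans of both HmgZ and HmgD, which encode HMG-box chromosomal proteins. The other 3 lay in Adf1 (2R:6662862-6663241, signal 2042), in CG32772 (X:4910054-4910557, signal 1996) and in Trl, the gene for GAGA factor (3L:14759318-14759736, signal 1908). Their summits were 791, 1258 and 1536 bp downstream of the nearest TSS.

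Replicate 1 gave 4456 peaks and replicate 2 gave 4361 peaks past the threshold of the irreproducible discovery rate (IDR), a ratio of 1.02. The conservative set, which comes from comparing the replicates with each other, held 5985 peaks, and the optimal set 6174. Of the replicate 1 peaks, 76.8% (95% exact binomial interval 75.6 to 78.1%) overlapped a peak of replicate 2, and 78.6% (77.3 to 79.8%) overlapped the other way. Uniform placement of summits within their chromosomes gave 2.15% and 2.19%. Peaks missing from the other replicate's set were weaker, with median signals of 59.8 against 109 in replicate 1 and 57.1 against 98.7 in replicate 2. Of them, 91.6% and 95.2% overlapped a ranked peak of any strength in the other replicate, against 37.2% and 38.4% under uniform placement. Of the stronger 50% of each set, 96.5% and 96.3% were in the other replicate's full set.

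Across 6149 peaks of the optimal set, the signals of the 2 replicates had a Spearman correlation of 0.793 and a Pearson r of 0.822 on the log scale; peaks are not independent replicates, so no p-value is given. The log2 ratio of the replicates had an SD of 0.60, against 0.60 and 0.64 between the random splits (pseudoreplicates) of replicate 1 and of replicate 2 over the same peaks. The ratio of the replicate spread to the mean of the other 2 was 0.974 (95% bootstrap interval 0.938 to 1.01). The ratio was 1.69 when 2 choices were changed together, with rows of identical coordinates for the replicates (SD 0.73) and the pseudoreplicates taken over each library's own thresholded peaks (SD 0.41 and 0.45). Each random split holds only part of the reads of its library, so it carries more sampling noise than a full replicate. A ratio of 1 is therefore not what sampling noise alone would give. The value of 0.974 does not show that the replicates differ by such noise only. Both versions of the ratio were chosen after seeing the data, and the one that gave 1.69 was run first. Whether the replicates differ by more than sampling noise is left open.

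Peak summits were concentrated at transcription start sites. Of 6148 summits on the major chromosomes, 3611 (58.7%, 95% interval 57.5 to 60.0%) lay within 500 bp of a TSS, a zone that covers 13.6% of the bases, and the exact two-sided binomial p was too small for double precision to hold. Coding exons held 2.13% of the summits against 13.7% of the bases (adjusted exact p = 1.0e-223), 3′ untranslated regions (UTRs) 0.830% against 4.40% (1.3e-61), introns 26.1% against 39.4% (1.3e-105) and intergenic sequence 10.9% against 27.3% (4.9e-218). The share in 5′ UTRs beyond 500 bp of a TSS was 0.504% against 0.779% (adjusted exact p = 0.016) and turned to an excess of 1.23 times when each gene was given 1 TSS. Other exons showed no difference past the threshold (adjusted exact p = 0.57). The median distance to the nearest TSS was 238 bp.

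**Figure D1:**
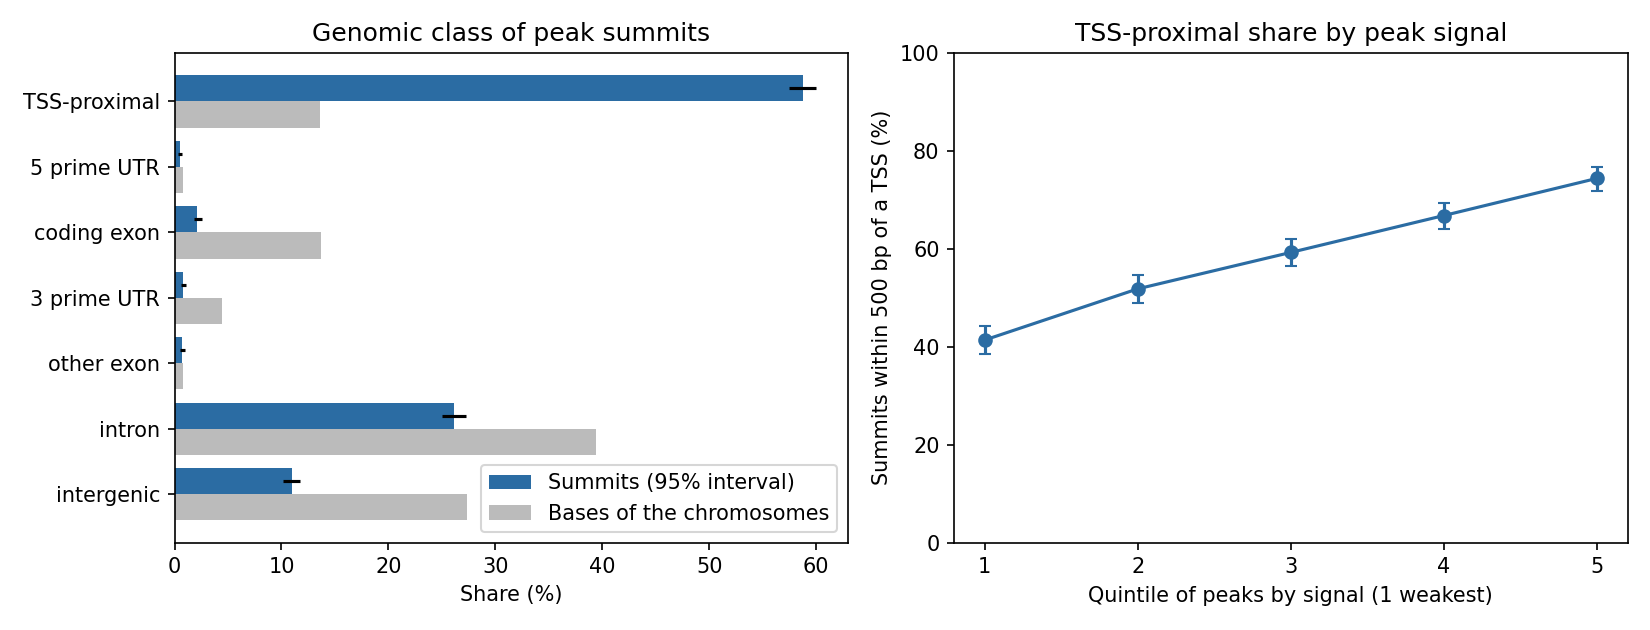
Left, share of peak summits of the optimal set (blue, with 95% exact binomial intervals) and share of chromosome bases (grey) in each genomic class, in percent. Right, share of summits within 500 bp of a TSS, in percent with the same intervals, for quintiles of the peaks ordered by signal. TSS-proximal sequence holds 58.7% of the summits and 13.6% of the bases, and the share rises from 41.4% in the weakest quintile to 74.4% in the strongest.

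TSS-proximal peaks were also stronger than distal ones. The median signal was 154 over 3611 proximal peaks and 109 over 2537 distal peaks, a difference of 44.8 (two-sided permutation p = 1e-05, the smallest that the permutations can give). In the replicates alone the difference was 19.8 in replicate 1 and 17.9 in replicate 2, with the same p. From the weakest to the strongest quintile of peaks by signal, the proximal share was 41.4%, 51.8%, 59.3%, 66.8% and 74.4%.

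The major arms carried similar densities, from 44.5 peaks per Mb on 3R to 48.3 on 2L. These counts leave out the peaks past the IDR threshold that are absent from the optimal set, most of which lay on 3R. Densities were not recomputed with them, so the low place of 3R and the calls per arm may depend on their absence. Relative to chromosome length, 2L (1.08 times the expected number, adjusted exact p = 0.011) and 2R (1.07 times, adjusted exact p = 0.024) were above the mean, and 3L, 3R and X did not pass the threshold. The expected numbers spread all peaks over a length that includes chromosome 4 and Y, which were nearly empty. This raises the ratio of every other arm, against TSSs as well. Ratios without chromosome 4 and Y were not computed, so the calls for 2L, 2R and X may rest on including them. Against the share of annotated TSSs the order changed, with 3L (1.08 times, adjusted exact p = 0.0059) and X (1.09 times, adjusted exact p = 0.0036) above it and the 2L and 2R ratios at 0.952 and 0.955. The calls for 2L and 2R ended without replicate 2 (adjusted exact p = 0.30 and 0.28), and that for 2R also in the stronger 50% of the peaks (0.34) and at a global IDR of 0.001 (0.18). X was above its share of length without replicate 1 (1.11 times, adjusted exact p = 0.0019) and without replicate 2 (1.13 times, 0.00039), in the conservative set (1.09 times, 0.0034), in the stronger 50% (1.10 times, 0.024) and at a global IDR of 0.001 (1.13 times, 0.00062), so its result rests on the peak set. Chromosome 4 held 2 peaks against 60.3 expected from its length (adjusted exact p = 5.5e-23), and Y held 1 against 164 (1.6e-69). The thresholded sets of replicates 1 and 2 held 3 and 4 peaks on chromosome 4. Ranked peaks of any strength were also rare on chromosome 4, with 15 in the pooled table, 29 in that of replicate 1 and 21 in that of replicate 2. Of its 80 protein-coding genes, 1 was bound. The Y chromosome held ranked peaks outside the thresholded sets at 169 per Mb, against 794 to 920 per Mb on the 5 major arms.

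A gene was counted as bound when a summit lay within 500 bp of any of its TSSs, which held for 4330 of 13968 protein-coding genes (31.0%). The word bound thus stands for a nearby peak, whether or not its signal depends on CG3847. Of 28 gene lists, 10 had more bound genes than the other genes, 7 had fewer, and 11 did not pass the threshold (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over the lists). The same 10 lists had more bound genes when only genes with a ranked peak of any strength within 500 bp of a TSS were counted, a background chosen after seeing the data. Peaks past the IDR threshold that are absent from the optimal set were not counted. Regions of such peaks overlap members of several lists, such as trx, ush, Syx1A and RpL13A. The counts and calls of the lists were not recomputed with these peaks.

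Cytoplasmic ribosomal protein genes had the highest bound share of the 28 lists, and other lists of gene expression machinery also had more bound genes. Among cytoplasmic ribosomal protein genes 71 of 86 were bound (82.6%, log2 odds ratio 3.38, adjusted exact p = 4.8e-22), led by RpL23A, RpL34b, RpL7 and RpS27 with signals of 1054, 956, 929 and 847. Mitochondrial ribosomal protein genes were bound in 44 of 73 cases (60.3%, log2 odds ratio 1.76, adjusted exact p = 1.0e-06), with mRpL41, mRpS10, mRpS23 and mRpL23 the strongest. Translation factors were bound in 28 of 53 cases (52.8%, log2 odds ratio 1.32, adjusted exact p = 0.0020), among them eIF6, eIF3c, eEF1gamma and eIF5B. Splicing and mRNA processing genes reached 21 of 29 (72.4%, log2 odds ratio 2.50, adjusted exact p = 1.5e-05), among them U2af50, CstF64 and SF2. The call for mitochondrial ribosomal proteins ended among genes with no other gene's TSS within 1000 bp on the other strand (adjusted exact p = 0.84), and that for splicing genes ended in the stronger 50% of the peaks (adjusted exact p = 0.065).

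Genes for energy metabolism, protein turnover and cell division were also bound above the other genes. Respiratory chain genes were bound in 42 of 87 cases (48.3%, log2 odds ratio 1.06, adjusted exact p = 0.0020), led by ND-ASHI, COX6B, COX5B and ND-MWFE. Proteasome genes were bound in 24 of 43 cases (55.8%, log2 odds ratio 1.49, adjusted exact p = 0.0020), led by Rpt2, Rpn6, Rpn5 and Rpn2. Cell cycle and replication genes were bound in 25 of 34 cases (73.5%, log2 odds ratio 2.59, adjusted exact p = 1.3e-06), led by Dp, the partner of E2F proteins, dpa, dup and the mitotic kinase gene polo. The respiratory chain call ended with replicate 2 left out (adjusted exact p = 0.26), at a global IDR of 0.001 (0.32, an alternative chosen after seeing the data) and in the stronger 50% of the peaks (0.24), and the proteasome call ended there as well (0.065).

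Genes for chromatin proteins were a further group with many bound members. Insulator and architectural protein genes were bound in 13 of 19 cases (68.4%, log2 odds ratio 2.21, adjusted exact p = 0.0020), with Chro, Cp190, pzg and Trl the strongest at 1721, 836, 538 and 428. Polycomb and trithorax genes were bound in 16 of 28 cases (57.1%, log2 odds ratio 1.56, adjusted exact p = 0.011), with ph-p, brm, E(z) and Trl the strongest. A mixed list of regulators with the zinc finger associated domain and of other C2H2 zinc finger regulators was bound in 13 of 20 cases (65.0%, log2 odds ratio 2.01, adjusted exact p = 0.0044). This list includes CG3847 itself beside Phs, Kah and M1BP, and it shares pita, ZIPIC, dwg and M1BP with the insulator list. The insulator call ended in the conservative set (adjusted exact p = 0.076), with replicate 1 left out (0.088), in the stronger 50% (0.069) and at a global IDR of 0.001 (0.14). The Polycomb and trithorax call ended among genes with no other gene's TSS nearby on the other strand (0.076).

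Genes of patterning and tissue differentiation were not bound above the other genes. None of the 8 Hox genes was bound (95% interval up to 36.9%, adjusted exact p = 0.10), and segmentation genes were bound in 7 of 28 cases (0.64), with bcd and cad the strongest at 221 and 115. Dorsoventral patterning genes were bound in 3 of 20 cases (0.21; tin, 443, and pnr, 74.7), Notch signalling genes in 5 of 19 (0.87; E(spl)m3-HLH, 326, and Su(H), 245) and neuronal differentiation genes in 5 of 30 (0.17; elav, 1034, and Nrx-1, 335). The counts were 4 of 24 for muscle (0.23; sls and how), 2 of 16 for epidermis and cuticle (0.23; grh and Vajk1), 4 of 13 for glia and trachea (1; moody and trh), 7 of 20 for germline and pole cells (0.87; cuff and piwi) and 3 of 16 for heat shock (0.51; Hsp27 and Hsp83). Genes of gut, fat body and hemocytes were bound less often than others, in 2 of 23 cases (adjusted exact p = 0.036; fkh, 139, and ush, 83.7), a call that ended with replicate 2 left out (0.19), in the conservative set (0.15) and in the stronger 50% of peaks (0.10). A region of peaks absent from the optimal set, with a highest signal of 2992, also overlaps ush. Segmentation genes passed the threshold for fewer bound genes with replicate 1 left out (adjusted exact p = 0.029), with replicate 2 left out (0.013) and in the stronger 50% (0.042), and neuronal differentiation (0.046 and 0.048) and epidermis and cuticle genes (0.032 and 0.037) did so with replicate 2 left out and at a global IDR of 0.001. Neuronal differentiation genes also did so with 1 TSS per gene (0.038) and among genes with a ranked peak (0.034). Among genes with no other gene's TSS within 1000 bp on the other strand the direction turned for segmentation (log2 odds ratio 0.89, adjusted exact p = 0.32) and dorsoventral patterning genes (0.32, adjusted exact p = 0.84), without passing the threshold.

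Genes for non-coding RNA were bound less often than the remaining genes of all types. The shares were 254 of 3289 for long and other non-coding RNA (7.72%, adjusted exact p = 1.9e-173), 13 of 290 for tRNA (4.48%, 1.4e-20), 16 of 269 for snoRNA (5.95%, 3.4e-16) and 10 of 330 for pseudogenes (3.03%, 1.4e-27). The snRNA genes, 7 of 32 bound, did not pass the threshold (0.87). The bound members with the strongest peaks included tRNA:Tyr-GTA-1-8, snoRNA:Psi18S-1275, snRNA:U1:95Ca, CR15345 and lncRNA:CR44463, which shares its peak with mRpL41. No rRNA gene of 99 (adjusted exact p = 1.4e-12) and no replication-dependent histone gene of 111 (8.9e-18) was bound. Of these, 1.01% and 2.70% had a ranked peak of any strength near a TSS, against 78.4% of protein-coding genes, and both calls ended among genes with such a peak (adjusted exact p = 1 and 0.38).

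**Figure D2:**
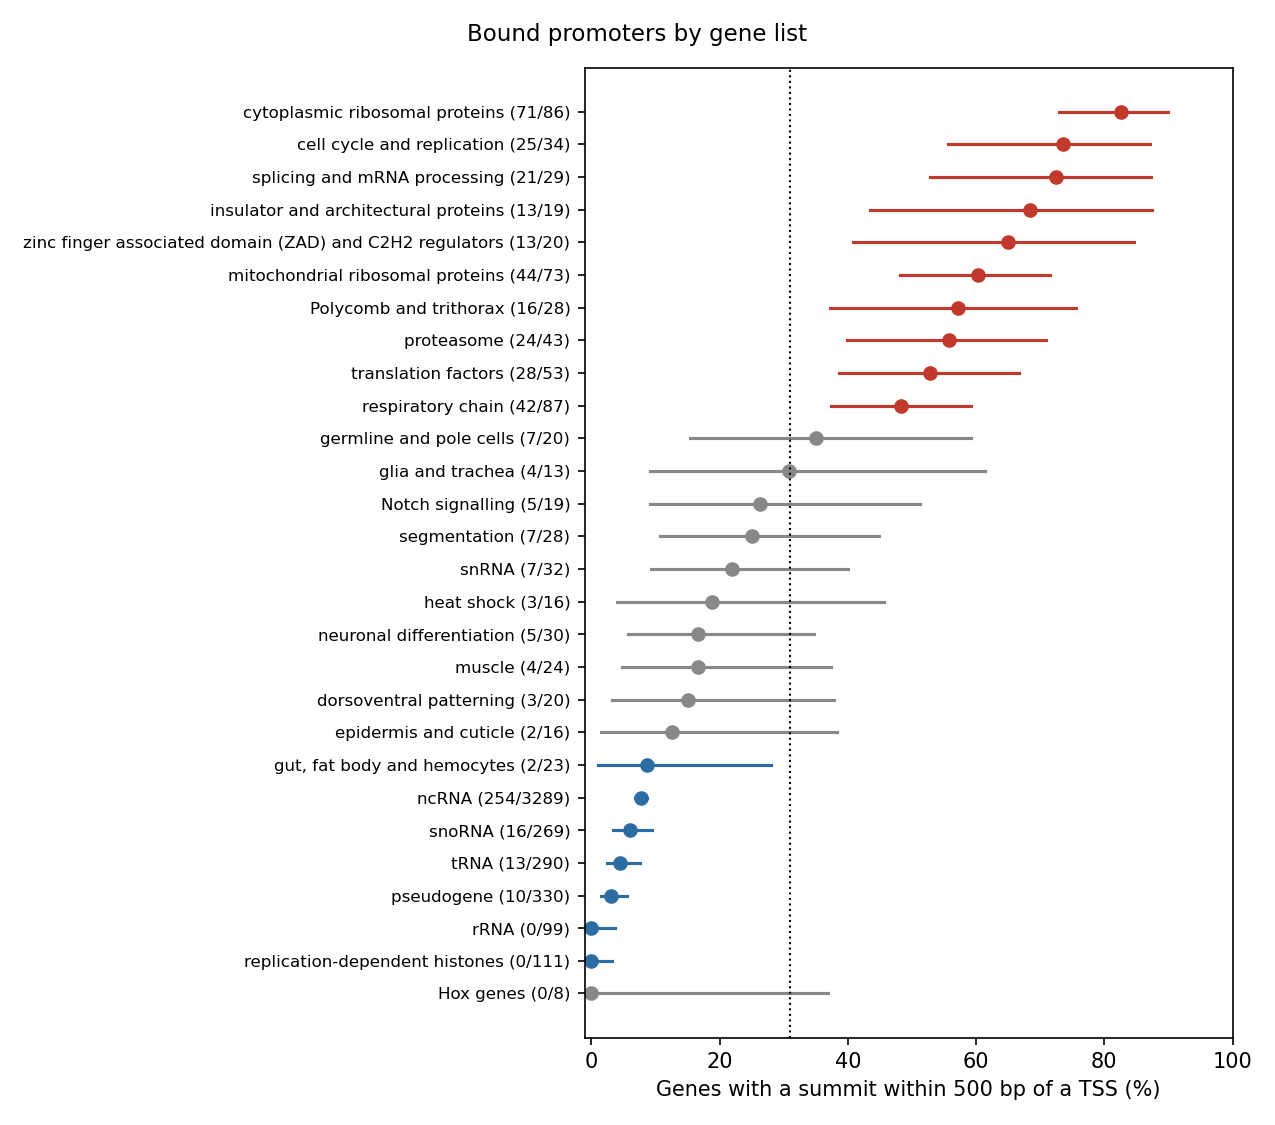
Share of genes with a summit within 500 bp of a TSS, in percent, for each gene list (points) with 95% exact binomial intervals (lines); bound and total genes are in brackets, and the dotted line marks the 31.0% of all protein-coding genes. Red lists lie above and blue lists below the other genes past the threshold, and grey lists did not pass. Cytoplasmic ribosomal protein genes have the highest share, 82.6%, and rRNA, replication-dependent histone and Hox genes are at 0.

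Bound genes often had a neighbour starting close by on the other strand. Among 4330 bound protein-coding genes, 2756 (63.6%) had a head-to-head protein-coding TSS within 1000 bp, against 2296 of 9638 unbound genes (23.8%). The log2 odds ratio was 2.48, and the p of Fisher's exact test was too small for double precision to hold. A summit between 2 close starts can mark both genes as bound, so the counts of bound genes are not counts of independent peaks. Examples are mRpS10 with Art3 and brm with Arl1.

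Sequence elements of constitutive core promoters were enriched under the summits. In 200 bp windows, the M1BP element GGTCACAC, also known as Ohler motif 1, was found in 6.16% of 6148 summit windows and 1.41% of 10638 background windows matched on GC content and TSS proximity (log2 odds ratio 2.20, adjusted exact p = 1.6e-60, Fisher's exact test, two-sided). The DNA replication-related element TATCGATA, the site of DREF, was in 6.33% against 1.76% (log2 odds ratio 1.91, adjusted exact p = 1.1e-51). Ohler motif 7, CAGCNSTG, was in 10.1% against 4.52% (1.24, adjusted exact p = 6.4e-42), and Ohler motif 6, GGTATTTT, was in 3.94% against 1.95% (1.05, adjusted exact p = 2.3e-13).

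Elements of 2 insulator proteins were enriched as well, at lower frequency. The CTCF core AGGKGGCGC was in 1.15% of summit windows against 0.216% of background windows (log2 odds ratio 2.41, adjusted exact p = 1.2e-13), and paired BEAF-32 half-sites were in 0.488% against 0.0940% (2.34, adjusted exact p = 3.6e-06). The half-site CGATA is also part of the DREF element TATCGATA, so the BEAF-32 enrichment is not independent of that of DREF. Of the 30 summit windows with paired half-sites, 29 were TSS-proximal. The elements of the insulator proteins Su(Hw) (0.520% against 0.479%, adjusted exact p = 0.77) and Pita (0.342% against 0.226%, 0.28) did not pass the threshold. The GAGA factor element was in 3.51% against 2.84% (0.32, adjusted exact p = 0.035), a call that ended in the conservative set (adjusted exact p = 0.24), without replicate 1 (0.93), without replicate 2 (0.26), with merged peaks (0.084) and in the stronger 50% (0.78), and turned to a lower share in 100 bp windows (log2 odds ratio -0.27). Poly-A tracts (4.42% against 7.13%), CA repeats (1.56% against 2.44%) and the Initiator (41.3% against 43.7%) were less frequent at summits, with adjusted exact p values of 2.8e-12, 0.00033 and 0.0057. All 3 calls ended against windows 1000 bp to either side, which are not matched on GC content: poly-A tracts (adjusted exact p = 0.81) and CA repeats (0.061) did not pass, and the Initiator was more frequent at summits (log2 odds ratio 0.13, adjusted exact p = 0.018). The remaining 12 of 22 motifs, Su(Hw) and Pita included, had log2 odds ratios from -0.32 to 0.60 and did not pass the threshold, though the TATA box passed against the windows to either side (log2 odds ratio 0.66, adjusted exact p = 6.5e-07). The background fell 1658 windows short of 2 per summit, and its mean GC content was 40.2% against 38.8% at summits. TSS-proximal windows were 52.3% of the background against 58.7% of the summits, so neither match was complete, and the second gap favours promoter elements.

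A search over all 8-mers, which did not use the list of known motifs, also returned the DREF and M1BP elements. On 2L, 3L, X and 4, 114 of 32896 8-mers were enriched at summits, and 92 of these were also enriched on 2R and 3R, which had not been used to find them (one-sided Fisher's exact test, Bonferroni adjusted). Overlapping 8-mers of 1 element can pass together, so these are not 92 elements. Some of the 92 hold only A and T, such as TATTTTAA (9.27% of summit and 4.81% of background windows on 2R and 3R, 3.2e-11) and ATTTAAAA (10.2% and 5.57%, 5.9e-11). Mean GC content was lower at summits than in the background (38.8% against 40.2%), so base composition can have helped such words to pass. The simulation without a planted word drew both groups from the same pool and could not show this. The lowest p on 2R and 3R belonged to the DREF element TATCGATA, in 6.80% of summit and 1.60% of background windows (1.9e-27), followed by the related ATCGATAG (1.3e-25) and by GGTCACAC (5.0e-25). Outside these elements, CAACACTG was in 4.25% against 0.621% of windows (7.1e-24) and CTGGCAAC in 4.25% against 0.798% (3.3e-20). The 8-mer GGCAACGC, the reverse complement of GCGTTGCC, was in 3.23% against 0.643% (1.9e-14), and CAGCACTG, a form of Ohler motif 7, was in 3.46% against 0.865% (1.2e-12). CTGGCAAC and GGCAACGC share the bases GGCAAC, so they may be parts of 1 element. With replicate 2 left out, 54 8-mers passed both steps, 48 of them among the 92.

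**Figure D3:**
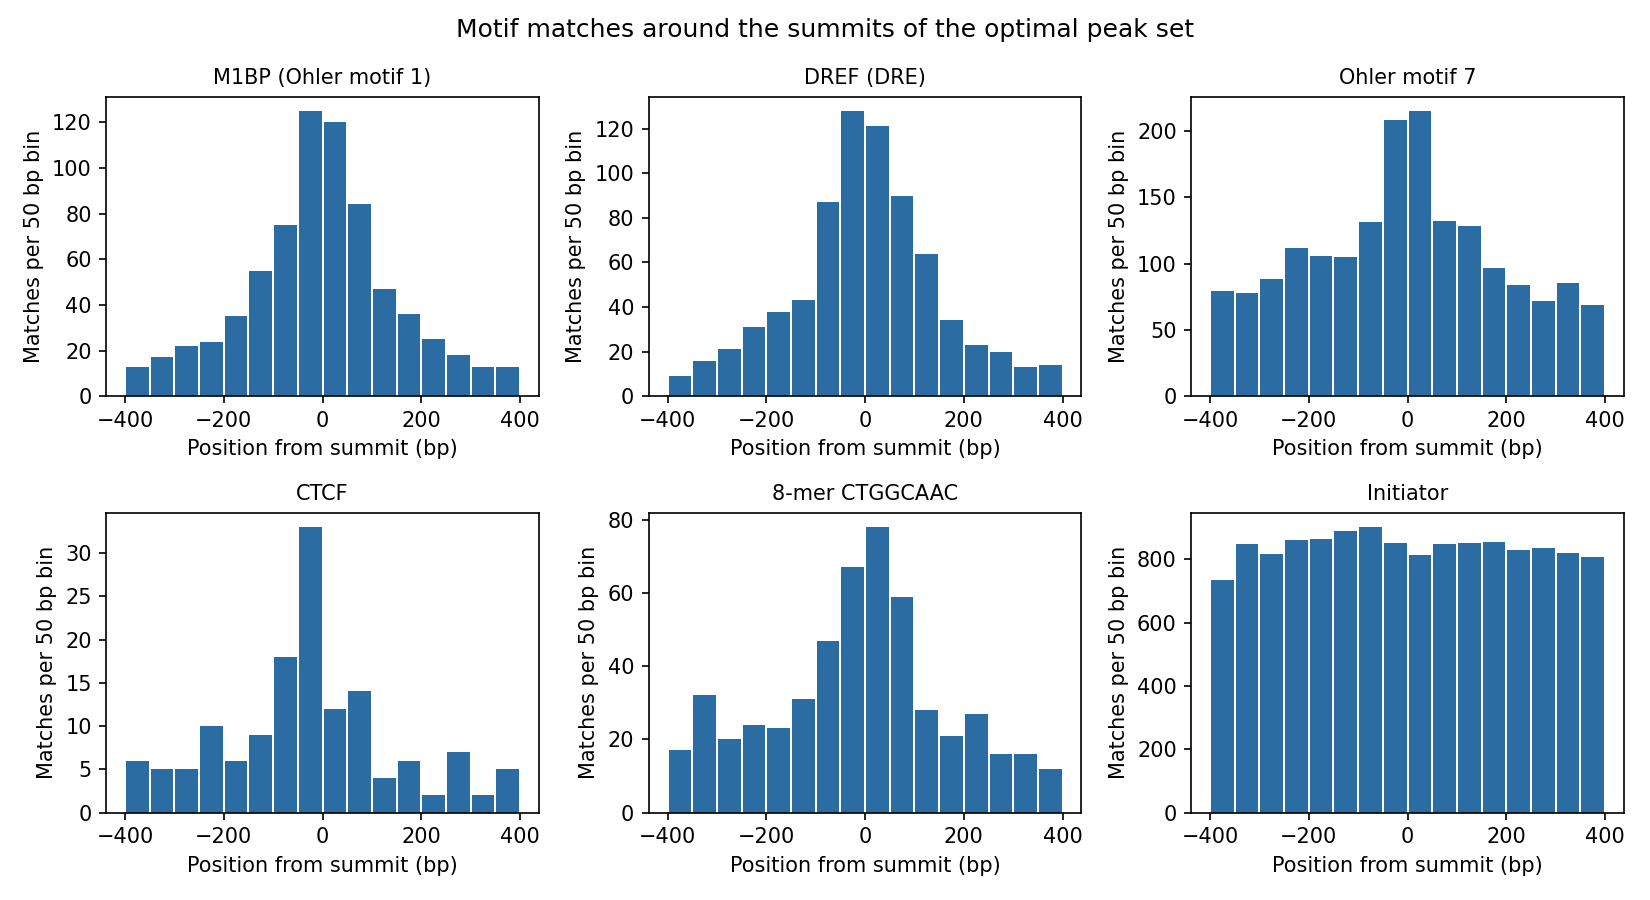
Number of motif matches on either strand in 50 bp bins from 400 bp before to 400 bp after the summits of the optimal peak set, for 6 elements. Matches to M1BP, DREF, Ohler motif 7, CTCF and the 8-mer CTGGCAAC are most frequent beside the summit, and those to the Initiator are spread evenly, with 1667 matches within 50 bp.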

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

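The ranked table of the pooled data holds 202 peaks past the IDR threshold that are absent from the optimal set and that the comparisons above do not use. Per the deposited file descriptions, an exclusion list of regions entered the thresholded sets. Whether these peaks lie in the listed regions was not tested. Their number was above the 3 that a count of 0 allows, but that bound takes no account of filtering, so no conclusion is drawn from it. On the major chromosomes 171 of the 202 peaks form 79 regions when peaks within 10000 bp of each other are joined. The strongest region, 2L:471144-482064, spans parts of ush, cbt, MED15 and CG4297 and holds 5 peaks with a highest signal of 2992. Others lie at Lk6 (3R:11758653-11764692, 3 peaks, highest signal 2077), at the trithorax group gene trx (3R:14283723-14287154, 3 peaks, 893) and at tara (3R:16223612-16255457, 10 peaks, 852). These regions were chosen by signal after the values were seen, and genes within them cannot be counted as unbound with the same firmness as others.

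The optimal set also holds 26 peaks on 20 unplaced scaffolds, which the comparisons leave out. Their median signal was 87.4, and the highest was 497.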

How the results depend on the processing

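The TSS-proximal excess, the higher signal of proximal peaks and the excess of divergent promoters kept their direction and their side of the threshold under every alternative run for them. For divergent promoters, none of the alternatives removed the marking of 2 genes by 1 summit, so they do not test that part of the excess. The planned limit of 0.01 on the global IDR removed no peak, because the deposited sets already use it, and is void. The causes of the changes below were not tested except where stated. Choices added after seeing the data were the IDR of 0.001, which left 3841 peaks, merged overlapping peaks, genes with a ranked peak near a TSS, and rows matched by identical coordinates (neither matching was planned), under which the Spearman correlation was 0.773. With that matching and the pseudoreplicates taken over each library's own thresholded peaks, 2 choices changed together, the ratio of spreads was 1.69. Depth per library is unknown here, so its limit on weak peaks could not be set.

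The shared share of replicate 1 and replicate 2 peaks was 65.5% and 66.9% with 50% overlap of both peaks, 72.1% and 73.6% with summits within 100 bp, and 80.9% and 82.4% in the stronger 50% of each set. The Spearman correlation of replicate signals was 0.364 over all ranked peaks, 0.825 in the conservative set and 0.754 in the stronger 50%. The ratio of spreads was 0.698 in the conservative set, which is itself chosen for agreement of the replicates. With 1 TSS per gene, 2 genomic classes passed the threshold with more summits than expected, TSS-proximal sequence and 5′ UTRs, which turned to 1.23 times; other exons turned to 1.03 times without passing it. With a replicate left out, the ratio for other exons ran from 0.683 to 1.06.

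Peak density on 3L was 0.990 times the expected in the stronger 50%, 0.983 at an IDR of 0.001, and from 0.971 to 1.01 with a replicate left out. On 3R it was 1.00 times with merged peaks. Against the share of TSSs, 2L was at 0.952, 2R at 0.955 and 3R at 1.00.

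In the stronger 50%, 6 lists had more bound genes in place of 10. Lists not past the threshold changed sign as follows, as log2 odds ratios. Glia and trachea was at -0.38 in the conservative set, -0.58 with a 200 bp window, -0.91 with 1 TSS per gene, -0.30 among genes with a ranked peak, and from -0.11 to 1.05 with a replicate left out. The snRNA genes were at 0.0785 in the conservative set, 0.0630 at an IDR of 0.001, 0.0294 with a 200 bp window, 1.51 among genes without a close neighbour, 0.21 among genes with a ranked peak, and from -0.79 to 0.0269 with a replicate left out. Notch signalling was at 0.17 in the stronger 50%, 0.50 with a 1000 bp window, and from 0.0802 to 0.28 with a replicate left out. Heat shock was at 0.0045 in the stronger 50% and 0.59 with a 1000 bp window. Among genes without a close neighbour, segmentation was at 0.89 and dorsoventral patterning at 0.32.

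The count of 8-mers passing both steps was 53 in the stronger 50%, 46 with 100 bp windows, 286 against windows 1000 bp to either side, which are not matched on GC content, and from 54 to 83 with a replicate left out. The GAGA factor motif turned to a log2 odds ratio of -0.11 in the stronger 50%, -0.27 in 100 bp windows and -0.0292 against the flanks, where the Initiator turned to 0.13. Among single genes, lists, motifs, classes and chromosomes, 1217 values under an alternative, leaving out the void one, kept direction and side of the threshold, 85 were no longer past it, 16 came to pass it and 33 changed direction. Of the 96 promoters taken by the rule for named genes, 67 were bound with a 200 bp window, 91 without replicate 1 and 92 without replicate 2. The rule took the 25 strongest of them only if both replicate sets held the peak, so the last 2 counts are raised by the choice.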

Other observations

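The comparisons of motifs by position, of motif matches around summits and of the replicate values at CG3847 were chosen after the data were seen, as were the tests of peaks with a signal under 20 and of ranked peaks outside the thresholded sets on chromosome 4.

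Distal and promoter summits were also tested apart for sequence elements, each set against its own part of the matched background. The distal background had 5074 windows, the full 2 per summit. The proximal background had 5564 and held the whole shortfall of 1658 windows, so its match on GC content was not complete. Among 2537 distal summits, the CTCF core was in 1.50% of windows against 0.158% (log2 odds ratio 3.20, adjusted exact p = 1.6e-10), the GAGA factor element in 3.15% against 1.81% (0.82, adjusted exact p = 0.0016) and the CG-rich octamer in 1.22% against 0.532% (1.21, adjusted exact p = 0.0081). The PHO element of the Polycomb group was less frequent there, in 7.88% against 10.5% (-0.45, adjusted exact p = 0.0016). Among 3611 TSS-proximal summits, DREF and M1BP elements were in 10.3% and 10.1% of windows against 2.93% and 2.43%, and the CTCF core was in 0.914% against 0.270% (1.74, adjusted exact p = 0.00011). In distal windows DREF and M1BP did not pass the threshold (adjusted exact p = 0.46 and 0.17). The difference between the proximal and the distal enrichments was not tested. These calls by position were made in the main setting only. Over all summits, the GAGA factor call ended in the conservative set and with either replicate left out.

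The enriched promoter elements were more frequent near the summits, to differing degrees. Per base, matches within 50 bp of a summit were 9.58 times as frequent as those 300 to 400 bp away for the DREF element, 8.75 times for M1BP, 3.30 times for Ohler motif 6, 2.72 times for Ohler motif 7, 12.8 times for the 8-mer ATCGATAG, 8.74 times for CAACACTG and 5 times for the CTCF core. The Initiator was at 1.04 times, Zelda at 0.744 times and GAGA factor at 0.369 times.

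A hypothesis set before its test was that promoter peaks with a core promoter element have a stronger signal. Of 4 elements, 0 had a higher median signal past the threshold. Ohler motif 7 had a median of 168 with and 152 without it (two-sided permutation test, adjusted p = 0.062), M1BP 140 and 156 (adjusted p = 0.062), Ohler motif 6 138 and 155 (0.13) and DREF 150.1 and 154 (0.59). The bound set in advance took an adjusted p of 0.05 or more, or a lower median with the element, as evidence against the hypothesis, and 3 of the 4 elements met its second part, by -16.3 (M1BP), -16.7 (Ohler motif 6) and -3.92 (DREF). Both parts were found too wide after the values were seen: a p that misses the threshold does not show equal medians, and a lower median counts only beyond its spread, which none of the 3 reached after adjustment (permutation p before adjustment 0.031, 0.099 and 0.59). No element showed the higher median that the hypothesis needs past the threshold, and the question stays open.

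The near absence of peaks on chromosome 4 extended to ranked peaks in no thresholded set, whose density was 0.0103 times that of the major arms, so the pattern is a low yield of peaks of any strength and not of strong peaks alone. Base composition is not the whole cause by this measure: with the rate of the other arms at matched GC content, 612 ranked summits would lie on chromosome 4, against 15 observed (95% exact Poisson interval 8.40 to 24.7). Nor is a sequence rich in transposable elements, since 167 windows of 50 kb on the other arms with at least as much such sequence held 437 ranked summits per Mb, against 11.1 on chromosome 4. These comparisons used the pooled ranked table and were not repeated with those of replicates 1 and 2, which held 29 and 21 peaks on chromosome 4. Control subtraction or filtering by the authors stays open and was not tested, and no biological explanation was tested.

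The peak at the CG3847 promoter lies in a stretch where ranked peaks in general are strong, and a candidate explanation is extra copies of the tagged locus, although how the construct was made is not given in the sources used here. The prediction, set before the test, was a median signal around the gene above the 95th percentile of X windows. The median of 62.5 over X:6337103-6359236, leaving out the promoter, was above 100% of 986 windows, whose 95th percentile was 30.2. Against windows on all major arms, the ratio to the median window was 1.63 in replicate 1, where 74 of 5233 windows were at least as high, and 2.74 in replicate 2, where 1 of 5200 was, so the locus stood out more in replicate 2. The promoter peak itself stood at 19.1 times the local median, so extra copies may raise its signal without making up all of it; the log2 ratio of replicate 2 over replicate 1 at this peak was 0.73, above 96.3% of 2269 promoter peaks found in every set, and no biological explanation was tested.

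Of the optimal peaks, 166 had a signal under 20, far below the median of 132. A candidate explanation is the pooled peak beside the peaks compared, a weak peak that passed on the strength of its neighbour: 100% of the 166 overlapped a stronger peak of the same set, against 2.76% of the other 6008 peaks. No biological explanation was tested.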
